A study of Macaca mulatta with 22 samples.

How the data were processed

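Total RNA from 22 day 12 corpus luteum samples of Macaca mulatta was amplified, labelled with biotin and hybridized to 1 Affymetrix rhesus array per sample, per the labels' protocols. The deposited values are linear signal intensity values made by the authors with MAS5 version 5.0, per the submitters' processing notes; scaling between arrays, filters and detection calls are not stated. In the deposited table the 2% trimmed mean intensity, which global scaling would make equal, differed 1.62-fold between arrays, from 45.3 to 73.5. The table holds 52865 probe sets, of which 99 controls were left out of the tests. The probe set annotation gave 1 gene symbol for 24969 probe sets, several for 361, which were not used as genes, and none for 27535.

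Values were floored at 16 and taken to log2. A rule fixed with the other choices before the data were examined called for quantile normalization if the medians of the log2 values of the arrays spanned over 1. They spanned 0.33 with the floor and 0.56 without it, so the values were used as deposited, and quantile normalized results are printed beside them; this was decided before any test. Probe sets were tested where their mean log2 value over all arrays was above the median of 4.22, a signal of 18.7, which left 26383. One limma fit (limma 3.58.1, R 4.3.3) held a mean per group for all 22 arrays, with eBayes and an intensity trend, 7 contrasts, and Benjamini-Hochberg adjustment over the probe sets of each contrast at a threshold of 0.05. For gene names the probe set with the highest mean stood for its gene, which gave 14132 genes, 9786 of them tested. Every adjusted p of a gene or probe set comes from limma.

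Before the data were examined, 19 pathway lists and 12 lists of cell type markers were fixed, and 30 of these had enough tested genes for a test. The exception was the B cell list, with 1 tested member. They were tested with camera at its preset correlation of 0.01, adjusted over all lists and contrasts together (210 tests). The tests were repeated with an estimated correlation, and with the mean of a gene's probe sets in place of its brightest one. None of the 29 calls held with an estimated correlation: the smallest adjusted p was then 0.853. Members past the threshold were counted over all probe sets and adjusted over the list alone.

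The naming rule was fixed at the same time. It takes the 8 largest rises and 8 largest falls among genes past the threshold whose groups do not overlap in the 4 contrasts between successive treatments, 4 each way in the others, up to 4 members past the threshold per list, 9 genes fixed by name, and, where fewer than 5 genes pass, the 5 of smallest p.

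Array measures were compared by exact two-sided permutation tests with Benjamini-Hochberg adjustment within each family of measures. These measures were the 3'/5' ratio of the actin and GAPDH controls, the trimmed mean, the mean log2 signal of marker lists, and the LH ablation score. The score's probe sets were chosen from Antide and Control arrays, so for those groups it describes its own selection. For comparisons that share arrays, unchanged groups were simulated 20 times and the shared arrays were split. Each probe set varied independently in these simulations, so they leave out variation that many probe sets share.

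The titles give replicate numbers shared between groups, and the labels do not say what they mark. Deviations of samples with the same number correlated at means of only -0.09 to 0.03, so the arrays were not treated as paired. In Antide+LH against Antide, 6 of 8 arrays still best matched their own number. Alternatives fixed beforehand were quantile normalization, a shift of each array to a common median, no filter, a stricter filter, an offset of 50 in place of the floor, no intensity trend, only the groups compared, array weights, the replicate number as a block, a minimum change of 2-fold, and each array left out in turn. The 3'/5' ratio as a covariate and the removal of 7 or 5 arrays of high ratio, the first and the removal of 7 also with quantile normalization, were added after the data were seen, as were the list tests with each array left out, and the LH ablation score with all its alternatives.

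The test was checked on simulated data of 26383 probe sets, with 100 changed at each of 2 sizes. Noise was drawn independently for each probe set, so false calls from variation shared between probe sets are not measured. A log2 change of 1 was recovered for 22% in Antide against Control, 15% in Antide+LH+TRL against Antide+LH and 19% in Antide+LH+TRL+R5020 against Antide+LH+TRL, and a change of 2 for 74%, 76% and 74%, with 2, 3 and 6 false calls. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.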

Results

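Gene expression was measured in 22 samples of day 12 corpus luteum from rhesus macaques (Macaca mulatta), each hybridized to its own Affymetrix rhesus array. The corpus luteum forms in the ovary after ovulation and secretes progesterone under luteinizing hormone (LH), a pituitary gonadotropin. Untreated Control samples (n = 4) were set beside 4 treatments: Antide alone (n = 5), Antide+LH (n = 4), Antide+LH+TRL (n = 4) and Antide+LH+TRL+R5020 (n = 5). Antide is an antagonist of gonadotropin-releasing hormone, and R5020 is a synthetic progestin. The labels do not spell out TRL; trilostane, an inhibitor of progesterone synthesis, is often abbreviated so, and the series title speaks of steroid ablation and replacement. The labels do not say whether samples came from separate animals, so p-values here measure the spread between samples.

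The trimmed mean signal of an array lay between 45.3 and 73.5. RNA integrity was read from the log2 ratio of 3' to 5' control probe sets of actin and GAPDH, which is higher where RNA is shorter. This 3'/5' ratio averaged 1.92 ± 0.97 (SD, n = 5) in Antide and 0.73 ± 0.06 (n = 4) in Control, with an exact two-sided permutation p = 0.0873 and an adjusted p = 0.306 over 21 tests. It averaged 0.84 ± 0.15 (n = 4) in Antide+LH, 1.18 ± 0.79 (n = 4) in Antide+LH+TRL and 1.27 ± 0.65 (n = 5) in Antide+LH+TRL+R5020. On 7 arrays it was above 1.2: Antide replicates 2 to 5, Antide+LH+TRL replicate 3, and Antide+LH+TRL+R5020 replicates 2 and 4.

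Antide against Control addressed LH ablation. STAR, CYP19A1 and some sterol synthesis genes fell, and CCL2 and some other chemokine and macrophage genes rose. STAR, which delivers cholesterol to mitochondria for steroid synthesis, fell by 3.41 ± 0.63 on the log2 scale (SE, 10.6-fold, limma adjusted p = 0.00728), from a geometric mean signal of 6230 in Control to 586 in Antide. CYP19A1, the aromatase that makes estrogen, fell by 5.07 ± 0.88 (33.7-fold, adjusted p = 0.00409). CCL2, a chemokine that draws monocytes, rose by 4.99 ± 0.86 (31.8-fold, adjusted p = 0.00372), from 38.7 to 1231. All Antide arrays lay beyond all Control arrays for these 3 genes. In all, 921 of 26383 probe sets changed, of which 487 rose and 434 fell. Counting only the probe set that stood for each gene, 382 of 9786 genes changed. Quantile normalization gave 2063 probe sets, of which 963 rose and 1100 fell, with 907 in common. Without the 7 arrays of high 3'/5' ratio, which leaves Antide replicate 1 as the only Antide array, 57 probe sets passed (49 rose and 8 fell), or 62 with quantile normalization (24 rose and 38 fell). Without the 5 arrays of very high ratio 457 passed (424 rose and 33 fell), and with the ratio as a covariate 1 did. The count was 42 with no filter, 1767 after a median shift and 1661 with array weights. Single arrays moved it over 1.5-fold: it was 281 (79 rose and 202 fell), 173 (56 rose and 117 fell), 456 (297 rose and 159 fell) and 566 without Control replicates 1, 2, 4 and 5, and 1848 (605 rose and 1243 fell), 301 and 455 without Antide replicates 1, 4 and 5. The near-even split into rises and falls thus held in some of these fits and not in others. The median log2 change of all tested probe sets was 0.03 with all arrays, 0.39 without the 7 arrays of high ratio and 0.3 without the 5.

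**Figure D1:**
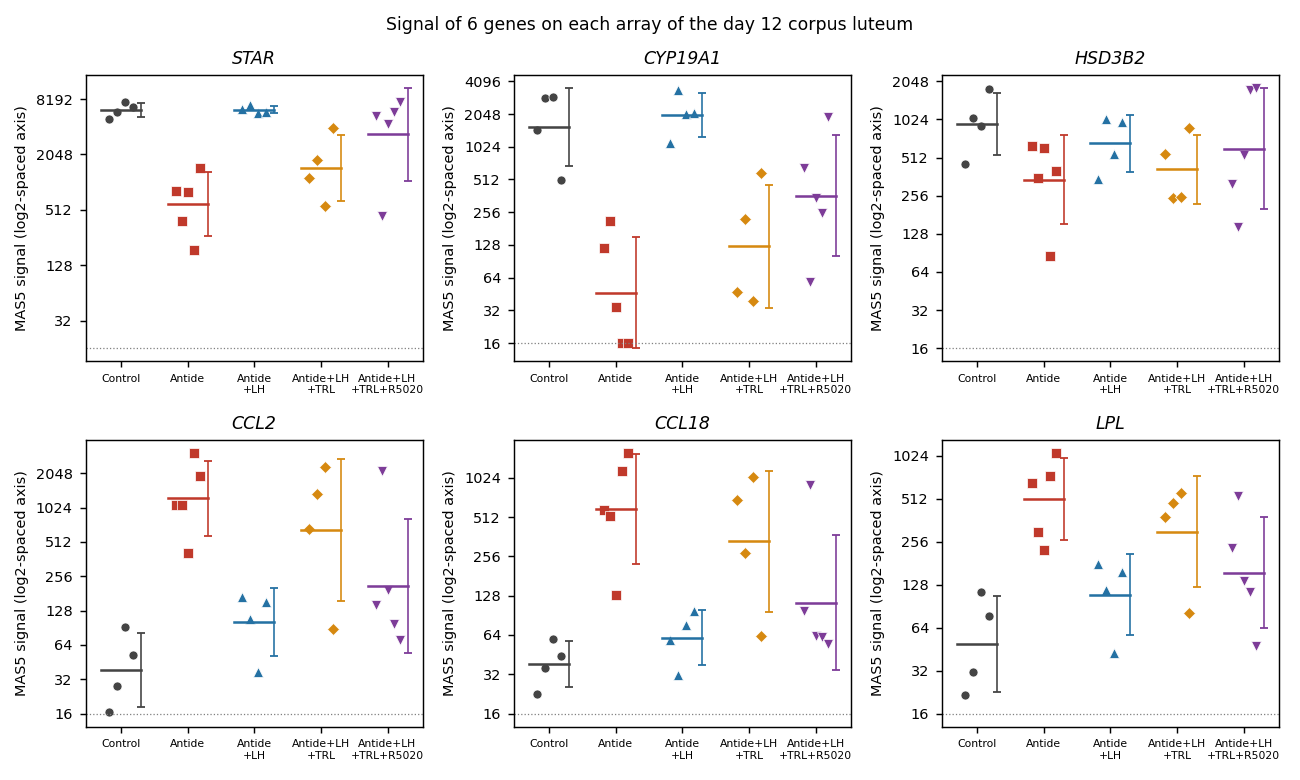
MAS5 signal (y axis, log2-spaced, arbitrary units) of STAR, CYP19A1, HSD3B2, CCL2, CCL18 and LPL on each array, by group (x axis); points are arrays, horizontal bars geometric means, whiskers 1 SD of the log2 values, and the dotted line the floor of 16. STAR lay between 4996 and 7621 on the Control arrays and between 185 and 1471 on the Antide arrays, and Antide+LH+TRL+R5020 replicate 2 lay at 435, apart from the other arrays of its group.

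Among the 14 tested genes of the steroid synthesis list, 0 rose, 3 fell (CYP19A1, STAR and POR) and 11 did not pass. Adjusted over the list alone, 5 fell. POR, which passes electrons to steroidogenic enzymes, fell by 0.88 ± 0.21 (adjusted p = 0.0214), while 3 other probe sets named POR had the opposite sign. HSD3B2, which makes progesterone, had a log2 change of -1.46 ± 0.64 (adjusted p = 0.198). The list as a whole lay lower, at a camera adjusted p = 0.00161, and an adjusted p = 0.853 with an estimated correlation. Of 15 tested cholesterol synthesis genes, 4 fell, 1 rose and 10 did not pass; adjusted over the list alone, 8 fell and 1 rose. Among these TM7SF2 (-2.90 ± 0.79), DHCR7 (-2.11 ± 0.41, with 3 of 5 Antide arrays at the floor of 16) and CYP51A1 (-1.97 ± 0.52) fell, all enzymes of late sterol synthesis, while INSIG1, a sterol sensor that restrains the pathway, rose by 1.49 ± 0.41. This list too lay lower (camera adjusted p = 0.00111, and adjusted p = 0.853 with an estimated correlation). Luteal steroidogenic cell markers lay lower at an adjusted p = 0.00111 (adjusted p = 0.853 with an estimated correlation), with 2 of 7 tested members falling, STAR and the prolactin receptor PRLR. Adjusted over the list alone, 5 of these fell. The luteal list shares STAR with the steroid list. On average the Antide arrays had the higher 3'/5' ratios given above, 1.92 against 0.73. Antide replicates 1 to 5, at ratios of 0.66, 2.36, 1.33, 2.09 and 3.18, had STAR signals of 830, 385, 793, 185 and 1471.

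The cytokine and chemokine list lay higher in Antide (camera adjusted p = 0.00726, and adjusted p = 0.853 with an estimated correlation). Of its 24 tested genes, 5 rose, 0 fell and 19 did not pass, and 9 rose when adjusted over the list alone. This call was lost with the 3'/5' ratio as a covariate (0.113) and without Antide replicate 2 (0.0637). Beside CCL2, the interleukin 1 receptor antagonist IL1RN rose by 3.84 ± 0.71 (adjusted p = 0.00728), CCL3 by 3.37 ± 0.89 and the matrix phosphoprotein SPP1 by 3.04 ± 0.68. CCL18, a macrophage chemokine outside the list, rose by 3.96 ± 0.77. Of 11 macrophage markers, CD68 rose by 2.56 ± 0.57, TYROBP by 2.54 ± 0.56 and CD14 by 1.92 ± 0.51, 0 fell and 8 did not pass; adjusted over the list alone 4 rose and 1 fell, and the list's camera adjusted p was 0.139. Matrix proteases MMP9, MMP19 and CTSK rose by 2.45 ± 0.67, 2.22 ± 0.47 and 1.37 ± 0.35, with 20 of 23 tested members of that list not past the threshold (9 rose and 1 fell when adjusted over the list alone, camera adjusted p = 0.082). COL6A3 and VCAN, collagen and proteoglycan genes of the matrix, rose by 1.74 ± 0.31 and 0.97 ± 0.27. In the immediate early and LH surge response list, PTX3, ATF3, CEBPD and KLF6 rose, by 2.89 ± 0.73, 2.02 ± 0.47, 1.96 ± 0.32 and 1.18 ± 0.33, and 17 of 21 did not pass (7 rose and 4 fell when adjusted over the list alone, camera adjusted p = 0.325). The mean 3'/5' ratio of these Antide arrays was higher too (1.92 against 0.73).

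Antioxidant enzymes lay lower in Antide (camera adjusted p = 0.0199, and adjusted p = 0.853 with an estimated correlation), with members in both directions. The glutathione transferases GSTA3 (-3.31 ± 0.80) and MGST1 (-2.18 ± 0.44) fell, the mitochondrial superoxide dismutase SOD2 rose by 2.67 ± 0.62, and 12 of 15 did not pass (1 rose and 3 fell when adjusted over the list alone). In the LH receptor and cAMP list, 4 of 21 fell and 0 rose, namely PRLR (-2.01 ± 0.48), the cAMP-activated exchange factor RAPGEF4 (-1.69 ± 0.36), the phosphodiesterase PDE7B (-1.57 ± 0.44) and the protein kinase A subunit PRKAR1A (-1.45 ± 0.30). Adjusted over the list alone 2 rose and 4 fell, and the camera adjusted p was 0.0705. LHCGR, CYP11A1, LDLR, SCARB1 and HMGCR carry no symbol in the probe set annotation and were not analysed here. In lipid handling, lipoprotein lipase (LPL) rose by 3.37 ± 0.64 and the lysosomal lipase LIPA by 1.25 ± 0.31, and the sterol carrier STARD4 fell by 1.85 ± 0.41. Further large rises by the naming rule were MAMU-AG (4.04 ± 0.60), PLAC8 (3.09 ± 0.78) and the stress-induced growth factor GDF15 (8.01-fold). Further large falls were LOC706293 (-4.15 ± 0.75), LOC713150 (-3.94 ± 0.81), ATXN7 (-3.88 ± 0.61), PSME3 (-3.73 ± 0.59), SERPIND1 (-3.63 ± 0.75), SERPINA4 (-3.61 ± 0.73) and CLIC5 (-3.57 ± 0.80). Where arrays of the lower group were at the floor, a change is a lower limit in size and its error does not cover this: DHCR7 and PDE7B were at it on 3 of 5 Antide arrays, PSME3, SERPIND1 and SERPINA4 on 2, CYP19A1, CLIC5 and PRLR on 1, and PTX3 on 2 of 4 Control arrays. MAMU-AG belongs to a family of near-identical MHC class I genes and another probe set of that name had the opposite sign, so its value is uncertain. FKBP5, a progestin-responsive chaperone, had a change of -0.12 ± 0.42 (adjusted p = 0.908), but its geometric mean signal was only 21 to 25.8 in the 5 groups, each with 1 or 2 arrays at the floor, so its changes in this and the other comparisons say little. Of 57 named genes past the threshold, 19 stayed past it whichever single array was left out, among them STAR, CYP19A1, CCL2, CCL18, IL1RN, LPL, DHCR7, PRKAR1A, RAPGEF4, CEBPD, MGST1 and COL6A3. The mean 3'/5' ratio of these Antide arrays was higher, as given above.

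Antide+LH against Antide addressed LH replacement, and the same luteal genes lay on the other side. CYP19A1 rose by 5.43 ± 0.88 (43.1-fold, limma adjusted p = 0.00655) and STAR by 3.42 ± 0.63 (10.7-fold, adjusted p = 0.0123), to a geometric mean STAR signal of 6278. CCL2 fell by 3.61 ± 0.86 (12.2-fold, adjusted p = 0.026), and CCL18 (-3.28 ± 0.77) and IL1RN (-3.19 ± 0.71) fell as well. Of 26383 probe sets, 965 changed: 741 rose (76.8%) and 224 fell. Quantile normalization gave 1723, of which 58.9% rose, and 935 were in common, and a median shift gave 1475, of which 57.6% rose. Without the 7 arrays of high 3'/5' ratio the count was 16 (4 rose and 12 fell), or 21 with quantile normalization (13 rose and 8 fell), without the 5 arrays of very high ratio 12 (0 rose and 12 fell), and with the ratio as a covariate 0. As deposited, falls thus outnumbered rises once arrays of high ratio were left out. The median log2 change of all tested probe sets moved as well, from 0.09 to -0.25 without the 7 arrays and -0.18 without the 5. With quantile normalization it was -0.01 without the 7, so the turn cannot be told apart from a shift in brightness. The count was 5 with no filter, 2887 with array weights and 183 (89.6% rose) with the replicate number as a block. It was 2733, 208, 1493, 151 and 95 without Antide replicates 1, 2, 3, 4 and 5, and 52, 126, 123 and 247 without Antide+LH replicates 1, 2, 3 and 4.

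Steroid synthesis genes lay higher with LH (2 of 14 rose, 0 fell, and 6 rose adjusted over the list alone), at a camera adjusted p = 0.0256, which was 0.0523 after quantile normalization, with an adjusted p = 0.853 with an estimated correlation. Cholesterol synthesis genes lay higher as well (TM7SF2 and DHCR7 of 15 rose, by 3.13 ± 0.79 and 1.84 ± 0.41, the latter with 3 of 5 Antide arrays at the floor, 0 fell, and 7 rose and 1 fell adjusted over the list alone), at 0.0455, 0.0855 after quantile normalization, and adjusted p = 0.916 with an estimated correlation. The steroid call ended without Antide replicate 1 (0.0639). The cholesterol call ended with the 3'/5' ratio as a covariate (0.109), without Antide replicates 1, 3 and 5 (0.0673, 0.057 and 0.0626) and without Antide+LH replicates 2 and 4 (0.156 and 0.0518). Luteal steroidogenic cell markers lay higher (2 of 7 rose, 4 adjusted over the list alone) at 0.00726, and adjusted p = 0.853 with an estimated correlation. Antioxidant enzymes lay higher at 0.0225 (adjusted p = 0.853 with an estimated correlation): GSTA3 rose by 3.47 ± 0.80, MGST1 by 2.37 ± 0.44, SOD2 fell by 2.32 ± 0.62, and 7 rose and 1 fell adjusted over the list alone. The 3'/5' ratio was 0.84 in Antide+LH against 1.92 in Antide (exact permutation p = 0.0873, adjusted p = 0.306).

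Cytokine and chemokine genes lay lower with LH at a camera adjusted p = 0.00726, which was 0.112 after quantile normalization, with an adjusted p = 0.853 with an estimated correlation. Of 24 tested, 5 fell, among them CCL2, IL1RN, CCL3 (-3.17 ± 0.89) and CXCL10 (-3.10 ± 0.88, with 3 of 4 Antide+LH arrays at the floor, adjusted p = 0.0485, or 0.0551 after quantile normalization), and 0 rose; adjusted over the list alone 8 fell and 3 rose. Macrophage markers lay lower at 0.0329, or 0.159 after quantile normalization (adjusted p = 0.853 with an estimated correlation), with TYROBP (-2.48 ± 0.56) and CD14 (-1.81 ± 0.51) falling among 11, and 3 falling adjusted over the list alone. The immediate early and LH surge response list lay lower at 0.0225, or 0.142 after quantile normalization (adjusted p = 0.853 with an estimated correlation). In it PTX3 (-2.68 ± 0.73), ATF3 (-2.04 ± 0.47) and CEBPD (-1.42 ± 0.32) fell, while TNFAIP6, a hyaluronan-binding protein of the ovulatory follicle, rose by 2.48 ± 0.51, and adjusted over the list alone 1 rose and 6 fell. Among steroid hormone receptors, the glucocorticoid receptor NR3C1 rose by 1.36 ± 0.27 and PGRMC1, a membrane component linked to progesterone binding, by 1.21 ± 0.34, NR2F1 fell by 1.09 ± 0.29, and 13 of 16 did not pass (2 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.86). The cytokine call ended with the 3'/5' ratio as a covariate (0.0839) and without Antide replicate 2 (0.0672). The macrophage call ended without Antide replicate 5 (0.0626) or Antide+LH replicate 3 (0.0612), and the immediate early call without Antide replicate 2 (0.165) or Antide+LH replicate 4 (0.0561). Further large rises were CLIC5 (3.83 ± 0.80), SERPIND1 (3.79 ± 0.75), LOC706293 (3.72 ± 0.75), ATXN7 (3.57 ± 0.61) and LOC713150 (3.51 ± 0.81), and further large falls PLAC8 (-3.12 ± 0.78), SLA (-2.84 ± 0.76) and IL33 (-2.82 ± 0.72). Changes are again lower limits in size for DHCR7 and CXCL10, for PTX3 and IL33 (2 of 4 Antide+LH arrays at the floor), IL1RN (1 of 4), SERPIND1 (2 of 5 Antide arrays), and CYP19A1, CLIC5 and PRLR (1 of 5). In the cAMP list PRLR (2.07 ± 0.48), RAPGEF4 (1.75 ± 0.36) and PRKAR1A (1.58 ± 0.30) rose, 0 fell and 18 of 21 did not pass (3 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.278). STARD4 rose by 1.84 ± 0.41, and HSD3B2 stood at 0.95 ± 0.64 (adjusted p = 0.421), PGR at 0.27 ± 0.25 and FKBP5 at -0.07 ± 0.42. Of 42 named genes past the threshold, CYP19A1, ATXN7, STAR and MGST1 (4 genes) stayed past it whichever array was left out. The same arrays, with 3'/5' ratios of 0.84 and 1.92, stand behind these groups.

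Of the 921 probe sets changed by LH ablation, 472 (51.2%) also changed the other way with LH replacement. Independent lists would share 16.3, and simulated unchanged groups on the same arrays shared 0, but neither allows for probe sets that move together. Both comparisons use the Antide arrays: with these split, so that each comparison had its own, the median number was 1 (0 to 82 over 20 arrangements). Across probe sets, which are not independent replicates, the log2 changes correlated at -0.89 (-0.44 in simulated unchanged groups) and at a median of -0.67 with the Antide arrays split. Their covariance was -0.324, against -0.049 in the simulated groups, a difference of -0.275. The count of 472 was 0 with the 3'/5' ratio as a covariate, 3 with no filter, 131 with the replicate number as a block and 1083 after quantile normalization. It was 168, 119 and 228 without Control replicates 1, 2 and 4, 1377, 133, 761, 80 and 65 without Antide replicates 1 to 5, and 44, 83, 77 and 164 without Antide+LH replicates 1 to 4.

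Antide+LH against Control asked whether LH-replaced corpora lutea still differed from untreated ones. STAR differed by a log2 change of 0.01 ± 0.67, CYP19A1 had geometric mean signals of 2010 and 1572, HSD3B2 a change of -0.50 ± 0.67 and FKBP5 a change of -0.19 ± 0.44. By limma 0 probe sets passed (smallest adjusted p = 0.394), with 718 at an unadjusted p under 0.05 where 1319 would come by chance, and 0 after quantile normalization. The fit estimates the spread of a probe set over all 5 groups. With only the groups compared 1660 were at an unadjusted p under 0.05, and with array weights 2094, both above 1319. In these fits too 0 passed (smallest limma adjusted p = 0.778 and 0.0774). The median of all tested probe sets was 0.13 higher in Antide+LH as deposited and 0.01 after quantile normalization, and list tests are relative to it. Against this shift cholesterol synthesis genes lay lower (median -0.23, camera adjusted p = 0.00726, and adjusted p = 0.853 with an estimated correlation), with 0 of 15 past the threshold over all genes or adjusted over the list alone. Red blood cell markers (0.0199, or 0.142 after quantile normalization) and the immediate early list (0.0313, or 0.16) lay lower too, both with adjusted p = 0.853 with an estimated correlation, and 0 of 3 and 0 of 21 genes past the threshold, the same when adjusted over the list alone. The cholesterol call ended without Control replicate 2 (0.217) or Antide+LH replicate 1 (0.0505), the red blood cell call without Control replicate 1 (0.297) or Antide+LH replicate 4 (0.0841), and the immediate early call without Control replicate 1 (0.292) or Antide+LH replicates 3 (0.132) or 4 (0.144). The genes of smallest p were MAMU-AG (3.36 ± 0.63), SLC25A52 (0.82 ± 0.22), HP (2.00 ± 0.57), LINGO3 (0.73 ± 0.21) and THBS1 (1.38 ± 0.40), and none passed (adjusted p = 0.394 for the first, 1 for the rest).

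Antide+LH+TRL against Antide+LH addressed steroid ablation with LH present. By limma 2 probe sets passed, both lower: a second probe set of CLIC5, a chloride intracellular channel, fell by 2.32 ± 0.36 (adjusted p = 0.0263, and 0.0555 after quantile normalization), with 2 of 4 Antide+LH+TRL arrays at the floor, and a second probe set of ALCAM, a cell adhesion molecule, fell by 2.87 ± 0.47 (0.0316 and 0.0555). Both fall outside the naming rule and were chosen after their values were seen. All 4 Antide+LH+TRL arrays lay below all 4 Antide+LH arrays for STAR, at a log2 change of -2.11 ± 0.67 (adjusted p = 0.611), and TNFAIP6 stood at -2.56 ± 0.54 (adjusted p = 0.334). The genes of smallest p were ALCAM by its brightest probe set (-1.84 ± 0.37, adjusted p = 0.224), TNFAIP6, TRIM47 (2.83-fold higher), SLC25A52 (-0.98 ± 0.22) and EPB41L4B (-1.14 ± 0.25), the last 3 at an adjusted p of 0.334 and none past the threshold. HSD3B2 stood at -0.68 ± 0.67, FKBP5 at 0.30 ± 0.44 and PGR at -0.29 ± 0.26. At an unadjusted p under 0.05 there were 1870 probe sets (1319 by chance). The count was 67 with array weights (7 rose and 60 fell), 8 with only the groups compared (1 rose and 7 fell, with 1 of the 2 in common), 3 with no filter (2 rose and 1 fell, 0 in common), 0 after quantile normalization and with the stricter filter, and 15 without the 7 arrays of high 3'/5' ratio (2 rose and 13 fell). Without the 5 arrays of very high ratio 1 passed, which rose and was neither of the 2. With single arrays left out 4 passed without Antide+LH+TRL replicate 4 and 0 without any of the other 7.

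The luteal and steroid lists lay lower under TRL, with 0 genes past the threshold over all genes. Luteal steroidogenic cell markers had a median of -0.68 (camera adjusted p = 0.0136, 2 of 7 falling adjusted over the list alone), and adjusted p = 0.853 with an estimated correlation. Steroid synthesis genes stood at a median of -0.44 (0.0256, or 0.0712 after quantile normalization, 2 of 14 falling adjusted over the list alone), cholesterol synthesis genes at -0.28 (0.0214, 1 of 15) and antioxidant enzymes at -0.40 (0.0194, 1 of 15), each with adjusted p = 0.853 with an estimated correlation. Cytokines and chemokines lay higher (median 0.45, 0.0142, or 0.142 after quantile normalization), as did matrix proteases and inhibitors (0.32, 0.0256, or 0.123), with adjusted p = 0.853 with an estimated correlation and 0 members past the threshold adjusted over the list alone. The 3'/5' ratio was 1.18 ± 0.79 in Antide+LH+TRL, where replicate 3 stood at 2.33, against 0.84 ± 0.15. Without this replicate the luteal (0.289), steroid (0.103), cholesterol (0.0607), antioxidant (0.0811) and protease (0.073) calls ended. So did the steroid (0.0506) and cholesterol (0.119) calls without Antide+LH replicate 2, and the protease call without Antide+LH replicate 3 (0.0612) or Antide+LH+TRL replicate 1 (0.0747).

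**Figure D2:**
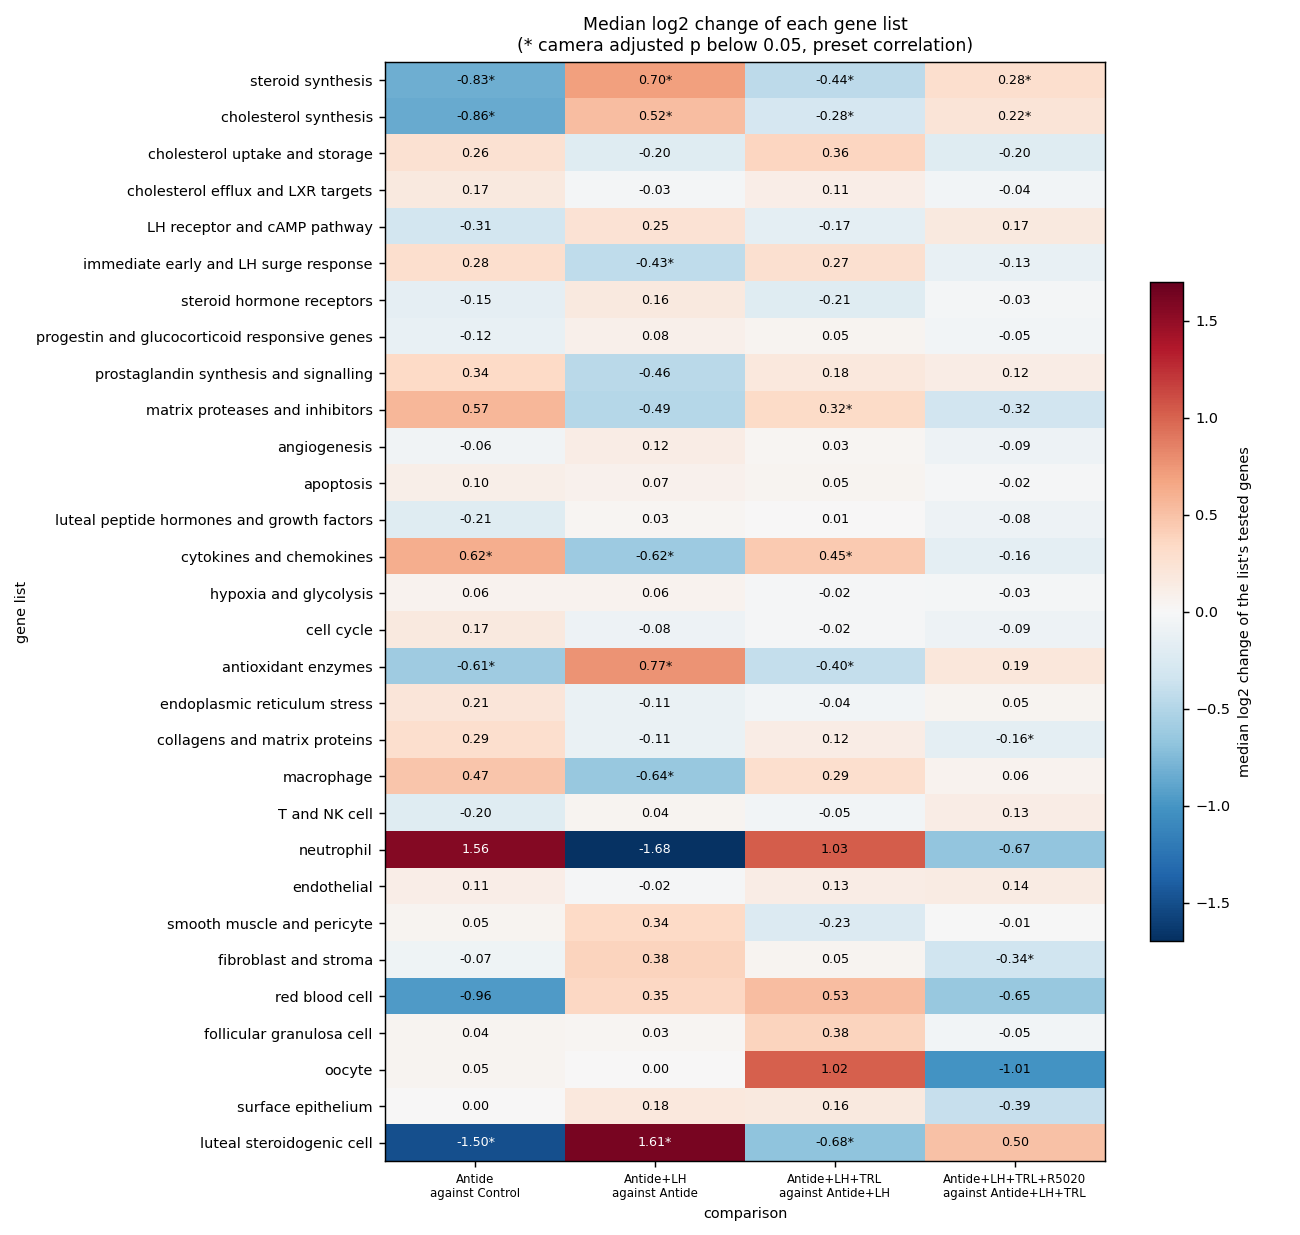
Median log2 change of the tested genes of 30 gene lists (rows) in 4 comparisons (columns); colours run from blue (lower) to red (higher), numbers are the medians, and an asterisk marks a camera adjusted p below 0.05 with the preset correlation. The steroid synthesis list stood at -0.83, 0.70, -0.44 and 0.28 from left to right; no list kept its call with an estimated correlation.

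To compare both ablations, each array was given an LH ablation score, the mean log2 signal of the 487 probe sets that rose in Antide minus that of the 434 that fell. Antide+LH+TRL arrays averaged 0.76 ± 0.97 (n = 4) and Antide+LH arrays -0.91 ± 0.33 (n = 4), a difference of 1.66 (exact two-sided permutation p = 0.0286, the smallest these samples can give). Adjusted over all 14 tests of the score this p is 0.0667, a family that holds the comparisons Antide against Control and Antide+LH against Antide, which the choice of probe sets fixed; adjusted over the other 10 tests it is 0.109, and adjusted p-values of the score below are of these 10. All 4 Antide+LH+TRL arrays lay above all 4 Antide+LH arrays. With any of Antide+LH replicates 1 to 4 left out, the exact p was 0.0571, at differences of 1.77, 1.61, 1.54 and 1.74. Of the 921 probe sets, 899 (97.6%) had the same sign in the 2 comparisons, which share no arrays, and a regression across them gave a slope of 0.51. Across all tested probe sets the changes correlated at 0.68, with a covariance of 0.176. Simulated unchanged groups gave 0, but there each probe set varied independently, so this is no reference for probe sets that move together. Both probe sets that passed under TRL had fallen with Antide as well. Independent lists would share 0.0329, which again does not allow for probe sets that move together. A direct test of the difference between the 2 changes passed for 0 probe sets by limma. At an unadjusted p under 0.05 there were 621, or 1066 after quantile normalization, where 0 passed too. LH ablation and steroid ablation were thus not shown to differ at any single probe set. The LH ablation score of Antide+LH (-0.91) lay 0.5 above that of Control (-1.41), at an exact permutation p = 0.0571 and adjusted p = 0.109. Its probe sets were chosen on these Control arrays, which can widen this difference.

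Antide+LH+TRL+R5020 against Antide+LH+TRL addressed progestin replacement. STAR signals were 4398 to 7575 on 4 of the 5 R5020 arrays and 435 on replicate 2, against 557 to 3944 under TRL, a log2 change of 1.23 ± 0.63 (limma adjusted p = 1). HSD3B2 stood at 0.54 ± 0.64. FKBP5 (-0.21 ± 0.42) and PGR (-0.04 ± 0.25) lay too near the floor to show a response to R5020, at geometric mean signals of 22.3 and 18.6 with it and 25.8 and 19.2 without. By limma 0 probe sets passed (641 at an unadjusted p under 0.05, 1319 by chance, and 0 after quantile normalization). The 641 became 550 with only the groups compared, 1473 with array weights and 1446 without Antide+LH+TRL+R5020 replicate 2. Without the 7 arrays of high 3'/5' ratio 2 passed, and 1 without Antide+LH+TRL+R5020 replicate 2. The genes of smallest p were SUOX (1.24 ± 0.32), LOC705269, MYO15B (-1.04 ± 0.28), DIPK1B (-1.09 ± 0.31) and BTBD1 (-1.06 ± 0.30), none past the threshold (adjusted p = 1). LOC705269 was at the floor on all 5 R5020 arrays and is given no fold.

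Cholesterol synthesis genes lay higher with R5020 (median 0.22, camera adjusted p = 0.0136, and adjusted p = 0.853 with an estimated correlation), and so did steroid synthesis genes (0.28, 0.0239, or 0.0712 after quantile normalization, and adjusted p = 0.853 with an estimated correlation). Collagens and matrix proteins lay lower (median -0.16, 0.0329, and adjusted p = 0.882 with an estimated correlation), as did fibroblast and stroma markers (-0.34, 0.0225, or 0.0712 after quantile normalization, and adjusted p = 0.853 with an estimated correlation). These lists share collagen genes. In all 4 lists 0 members passed over all genes or adjusted over the list alone. With the replicate number as a block 1 of the 4 calls was left, and with the mean of a gene's probe sets 3 were. Leaving out Antide+LH+TRL replicate 3 ended all 4 calls (0.143, 0.368, 0.169 and 0.103 in the order given). Without Antide+LH+TRL+R5020 replicate 6 the cholesterol (0.0523), steroid (0.148) and collagen (0.132) calls ended, and without its replicate 2 the collagen (0.0684) and fibroblast (0.159) calls. Leaving out this replicate 2 nonetheless gave 7 list calls in place of 4. Of the 7, 4 lay higher and 3 lower, and 2 were among the 4. The smallest camera adjusted p went from 0.0136 to 0.000165. The steroid call also ended without Antide+LH+TRL+R5020 replicate 3 (0.0696), the collagen call without its replicate 1 (0.168) or Antide+LH+TRL replicate 1 (0.0976), and the fibroblast call without Antide+LH+TRL replicate 4 (0.0792). The 17 progestin and glucocorticoid responsive genes had a median of -0.05 (camera adjusted p = 0.907). The LH ablation score was 0.12 ± 1.15 (n = 5) with R5020 against 0.76 ± 0.97 (n = 4), a difference of -0.64 (exact permutation p = 0.397, adjusted p = 0.421). It was -1.12 and -0.35 without Antide+LH+TRL+R5020 replicates 2 and 6, -0.22 without Antide+LH+TRL replicate 3, and 1.58 times as large without its replicate 4. Steroid ablation and progestin replacement shared 0 probe sets both ways; changes correlated across probe sets at -0.58, and at -0.53 in simulated unchanged groups, with covariances of -0.073 and -0.061. With the shared Antide+LH+TRL arrays split, the correlation was -0.09 (-0.29 to 0.14 over 6 arrangements).

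**Figure D3:**
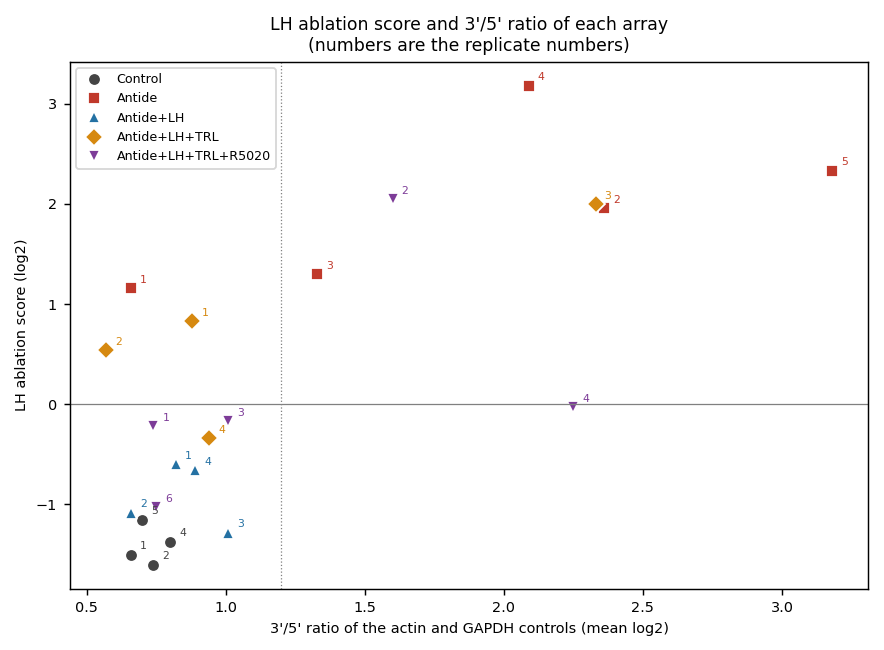
LH ablation score (y axis, log2) against the mean log2 3'/5' ratio of the actin and GAPDH controls (x axis) on each of the 22 arrays; symbols are groups, numbers are replicate numbers, and the dotted line marks a ratio of 1.2. Antide replicate 1 has a ratio of 0.66 and a score of 1.16, above all Control and Antide+LH arrays, and Antide+LH+TRL+R5020 replicate 2 lies at 2.05. The score's probe sets were chosen on the Antide and Control arrays, Antide replicate 1 included, which favours high scores on Antide arrays.

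Antide+LH+TRL+R5020 against Antide+LH asked how far R5020 stood from the LH-replaced group. STAR stood at -0.88 ± 0.63 and ALCAM at -1.24 ± 0.35 (both limma adjusted p = 0.975), HSD3B2 at -0.14 ± 0.64, FKBP5 at 0.08 ± 0.42 and PGR at -0.33 ± 0.25. By limma 0 probe sets passed (1247 at an unadjusted p under 0.05, 1319 by chance, and 0 after quantile normalization). The 1247 became 1471 with only the groups compared and 1856 with array weights. Macrophage markers (median 0.38, camera adjusted p = 0.0256, or 0.142 after quantile normalization) and cytokines (0.39, 0.0329, or 0.226) lay higher, and smooth muscle and pericyte markers lower (-0.36, 0.0455, or 0.142), with 0 members past the threshold over all genes or adjusted over the list alone, and adjusted p = 0.853 with an estimated correlation for all 3 lists. Antide+LH+TRL+R5020 replicate 2 stood apart in such genes, with a CCL2 signal of 2148 against 70.2 to 193 on the other arrays of its group. Without it the cytokine call (0.816, with the direction turned) and the macrophage call (0.139) ended, and with the 3'/5' ratio as a covariate the cytokine (0.195) and smooth muscle (0.0523) calls. The cytokine call also ended without Antide+LH replicates 1, 3 and 4 (0.0513, 0.0612 and 0.051) or Antide+LH+TRL+R5020 replicate 3 (0.0564), and the macrophage call without Antide+LH replicate 3 (0.0891) or Antide+LH+TRL+R5020 replicate 1 (0.372). The smooth muscle call ended without Antide+LH replicates 2, 3 and 4 (0.119, 0.183 and 0.0793) or Antide+LH+TRL+R5020 replicates 1 and 4 (0.1 and 0.275). It also ended with the mean of a gene's probe sets in place of the brightest one. The LH ablation score differed by 1.03 (exact permutation p = 0.0794, adjusted p = 0.109). The difference was 0.54 without Antide+LH+TRL+R5020 replicate 2, 1.31 (exact p = 0.0286) without its replicate 6, and 0.44 (exact p = 0.229) without the arrays of high 3'/5' ratio. The genes of smallest p were EPB41L4B (-1.04 ± 0.24), ZAP70 (1.42 ± 0.35), SLC16A1 (-1.36 ± 0.35), SORCS1 (-0.98 ± 0.27) and ALCAM, none past the threshold.

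Antide+LH+TRL against Antide compared groups that differ by LH and TRL together. STAR stood at 1.31 ± 0.63 (limma adjusted p = 0.893), with geometric mean signals of 1455 and 586, and VIL1 at 1.61 ± 0.38 and ITLN1 at 1.80 ± 0.44 (both 0.886). DDX51 (1.05 ± 0.26), IGFLR1 (-1.13 ± 0.29) and CARHSP1 (1.00 ± 0.27) were the other genes of smallest p. HSD3B2 stood at 0.27 ± 0.64, FKBP5 at 0.23 ± 0.42 and PGR at -0.01 ± 0.25. By limma 0 probe sets passed (1472 at an unadjusted p under 0.05, 1319 by chance, and 0 after quantile normalization), 6 without the 7 arrays of high 3'/5' ratio, and 1 without Antide replicate 2. Fibroblast and stroma markers lay higher (median 0.49, camera adjusted p = 0.0443, or 0.0712 after quantile normalization, and adjusted p = 0.853 with an estimated correlation), with 0 of 9 past the threshold over all genes or adjusted over the list alone. This call ended without Antide replicates 1 and 5 (0.0859 and 0.0541) or Antide+LH+TRL replicates 3 and 4 (0.202 and 0.0537). The LH ablation score had a difference of -1.23 (exact permutation p = 0.0873, adjusted p = 0.109), and of -1.64 (exact p = 0.0357) without Antide+LH+TRL replicate 3; its probe sets were chosen on these Antide arrays, which can widen it. PGR, the nuclear progesterone receptor, was at the floor on all 4 Control arrays and its highest signal on any array was 34.9.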

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

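All tests of explanations below, and the alternatives that use the 3'/5' ratio, were chosen after the results were seen. In each group of 4 or 5 arrays the gap of the highest or lowest array to its nearest neighbour was divided by the range of the group and set against Dixon's 95% critical value for its size (0.71 for 5 arrays). Over 394 such groups of values, 28 were beyond it, where chance gives about 20.

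Antide+LH+TRL+R5020 replicate 2 made up 17 of the 28, where an array would have 0.9 by chance if values were independent. Many of these genes were named for their change with Antide, so the 17 are not independent. On the LH ablation score the gap of this array was 0.68, under the critical 0.71. It was highest of its group for CCL18 (0.791), IL1RN (0.828), MMP19 (0.904), BIRC3 (0.902), BMP2 (0.852), LDHA (0.749) and CXCL10 (0.83). It was lowest for LOC706293 (0.729), LOC713150 (0.858), ATXN7 (0.75), SERPIND1 (0.766), CLIC5 (0.798), STAR (0.81), TM7SF2 (0.748), PRKAR1A (0.873), GSTA3 (0.737) and PGRMC1 (0.813). Antide replicate 5 was highest for the actin 3'/5' ratio (0.757) and lowest for MAMU-AG (0.803), and Antide replicate 4 lowest for ATF3 (0.867). Control replicate 1 was lowest for STARD4 (0.904) and highest for IL33 (0.916), and Control replicate 4 alone lay above the floor for BIRC3 (1). Antide+LH replicate 4 was highest for BIRC3 (0.921) and FKBP5 (0.984), Antide+LH replicate 3 for CXCL10 (1), Antide+LH replicate 2 was lowest for NR2F1 (0.887), and Antide+LH+TRL replicate 3 was highest for VCAN (0.912).

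The first pattern is the 921 probe sets changed by Antide, for which the 3'/5' ratio predicted a median share of 0.33 of the change, with slopes taken within the other 17 arrays (jackknife SE 0.19, 0.25 to 0.49 with single arrays left out, the highest without Antide+LH+TRL+R5020 replicate 4), 0.24 within all groups (SE 0.11) and 0.18 within Antide (SE 0.11), which argues against RNA integrity as the whole cause. The ratio as a covariate rests on the same slopes within all groups, so it is no separate evidence. It left a median change of 1.13 (SE 0.41) of 1.54 (SE 0.37), with all 921 signs kept. These probe sets were chosen for their change, so kept signs say little. The covariate ended all calls but 1 because the change shrank while its error grew. RNA integrity as part of the cause stays open, since the share lies under 2 of its standard errors from 0 by the slopes within the other groups and within Antide, and above 2 by the slopes within all groups. A lower share of luteal cells stays open too. Macrophage markers moved apart from the mean of 4 other cell types by 0.80 in Antide against Control (exact permutation p = 0.143). In Antide+LH against Antide they did so by -1.02 (exact p = 0.0159, not adjusted). Macrophage minus endothelial markers differed there by -0.76 (exact p = 0.0556, adjusted p = 0.524). Such a gap can arise with or without a change in the share of luteal cells, so it decides nothing. Brightness differences between arrays are argued against by the 907 probe sets past the threshold after quantile normalization, while LH ablation itself, the treatment the design names, stays open and untested.

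The second pattern is the shift of Antide+LH+TRL samples along the LH ablation changes. Without Antide+LH+TRL replicate 3, the array of high 3'/5' ratio, the difference in score was 1.25 (exact permutation p = 0.0286, the smallest possible), with all 3 remaining arrays above all Antide+LH arrays, which argues against RNA integrity. After quantile normalization the difference was 1.22 (exact p = 0.0286), which argues against brightness. A lower share of luteal cells stays open: luteal markers differed by -1.01 (exact p = 0.0286, adjusted p = 0.48) and macrophage minus endothelial markers by 0.27 (exact p = 0.514), and luteal markers cannot separate fewer cells from lower expression per cell. The loss of steroids in the presence of LH, which the design names, stays open as a hypothesis found on the same samples.

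The third pattern is Antide+LH+TRL+R5020 replicate 2, whose LH ablation score of 2.05 lay within the Antide range while the other arrays of its group averaged -0.36. From its 3'/5' ratio a score of -0.09 (prediction SD 0.52) was predicted, which argues against RNA integrity. An exchange with Antide+LH+TRL replicate 4, the array of its group with the lowest score (-0.34), might account for it, but the gap of that array was 0.38 of its group's range and that of replicate 2 was 0.68, both under the critical values, so an exchange cannot be told apart from variation between samples. A single wrong label, or a sample that did not respond to R5020, was not tested. All arrays were kept in the groups their labels give.

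Other splits of the same arrays gave as many changed probe sets as follows. For Antide against Control 3 of 100 splits, the real one included, reached the real 921, a share not adjusted over the 7 contrasts. The highest other, 1611, set Antide replicate 1 with the 4 Control arrays, at mean 3'/5' ratios of 0.71 and 2.24. A grouping along the ratio thus gave more calls than the treatments, and chance is made less likely but not excluded. For Antide+LH against Antide 1 of 100, the real one, reached 965 (highest other 517), so no other grouping tried gave as many. For Antide+LH+TRL against Antide+LH 1 of 35 reached 2 (highest other 0), the smallest share that 35 splits can give. Resting on 2 probe sets, this does not exclude chance. The count was 0 after quantile normalization and without any one of 7 of the 8 arrays. Where the real count was 0, each split reaches it, so the splits decide nothing: this held for 35 of 35 splits of Antide+LH against Control (highest other 1), and 100 of 100 for Antide+LH+TRL+R5020 against Antide+LH+TRL (76), for Antide+LH+TRL+R5020 against Antide+LH (2) and for Antide+LH+TRL against Antide (2434). The split with 2434 set Antide+LH+TRL replicate 3 and Antide replicates 2, 4 and 5 against the rest, with mean 3'/5' ratios of 2.49 and 0.87, which points to a structure of the samples. These 4 arrays also have the highest LH ablation scores of both groups (1.96 to 3.18, against 1.30 or lower), and no test separates the ratio from the score here. The split with 76 set R5020 replicates 3, 4 and 6 and TRL replicates 1 and 4 against the rest, at ratios of 1.17 and 1.31.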

How the results depend on the processing

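The alternatives that use the 3'/5' ratio, the list tests with each array left out, and the LH ablation score with all its alternatives were added after the data were seen; the others were planned. Counts are in the order Antide against Control, Antide+LH against Antide, and LH ablation and replacement both ways, with 921, 965 and 472 as reported. They were 2063, 1723 and 1083 after quantile normalization, 1767, 1475 and 900 after a median shift, 42, 5 and 3 with no filter (52766 probe sets tested, 9115 of them at the floor on all arrays), and 1661, 2887 and 1236 with array weights. With the 3'/5' ratio as a covariate they were 1, 0 and 0 (37, 0 and 0 with quantile normalization), without the 7 arrays of high ratio 57, 16 and 16 (62, 21 and 21 with quantile normalization), and without the 5 arrays of very high ratio 457, 12 and 12. Of the first 2 counts, 86% and 25% rose without the 7 (38.7% and 61.9% with quantile normalization) and 92.8% and 0% without the 5, against 52.9% and 76.8% as reported. Where 7 arrays were left out, the lone Antide array was assumed to vary like the other groups. Antide+LH+TRL against Antide+LH went from 2 to 0 (quantile normalization, stricter filter, quantile normalization with the covariate), 1 (offset, a fall in common), 1 (without the 5 arrays, a rise not in common), 3 (no filter, 2 rose, 0 in common), 8 (only the groups compared, 1 rose, 1 in common), 67 (array weights, 7 rose), 15 (without the 7, 2 rose) and 6 (quantile normalization without the 7, 2 rose). Counts of 0 became, for Antide+LH against Control, 1 with no filter, with the covariate and without the 5 arrays; for Antide+LH+TRL+R5020 against Antide+LH+TRL, 2 with no filter, without the 7 and without the 5, 1 with array weights and 3 with quantile normalization without the 7; for Antide+LH+TRL+R5020 against Antide+LH, 1 with no filter; and for Antide+LH+TRL against Antide, 4 with no filter, 6 without the 7 and 2 with quantile normalization without the 7. Steroid ablation and progestin replacement shared 2 with no filter and without the 7, 1 with array weights and without the 5, and 3 with quantile normalization without the 7, in place of 0. LH and steroid ablation shared 41 with array weights, 1 with the offset and with quantile normalization without the 7, and 0 with quantile normalization, no filter, stricter filter, the covariate, both together and without the 5, in place of 2. Of 29 list calls, 13 were left after quantile normalization and 0 with an estimated correlation. With the mean of a gene's probe sets 2 calls ended and 14 others came to pass. For the covariate, sizes and errors before and after are given with the weighing of LH ablation; for the others the cause was not tested.

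With each array left out, counts ran from 173 (without Control replicate 2) to 1848 (without Antide replicate 1) for Antide against Control, 52 (without Antide+LH replicate 1) to 2733 (without Antide replicate 1) for Antide+LH against Antide, 44 to 1377 (the same arrays) for both ways, 0 to 1 for Antide+LH against Control (without Antide+LH replicate 3), Antide+LH+TRL+R5020 against Antide+LH+TRL and the steroid overlap (without Antide+LH+TRL+R5020 replicate 2) and Antide+LH+TRL against Antide (without Antide replicate 2), and 0 to 4 (without Antide+LH+TRL replicate 4) for Antide+LH+TRL against Antide+LH and its overlap with LH ablation. Antide+LH+TRL+R5020 against Antide+LH stayed at 0. List calls with each array left out ran from 19 (without Antide+LH+TRL replicate 3) to 35 (without Antide replicate 4, among others), and the adjusted p of the cytokine list in Antide+LH+TRL+R5020 against Antide+LH from 0.00099 (without Antide+LH+TRL+R5020 replicate 4) to 0.816 (without its replicate 2). With the replicate number as a block, Antide+LH against Antide gave 183 and both ways 131, with Antide against Control at 617 and no other count of probe sets moved over 1.5-fold. List calls with the block went from 4 to 1 in Antide+LH+TRL+R5020 against Antide+LH+TRL (cholesterol 0.0626, steroid 0.151 and collagen 0.154), from 3 to 5 in Antide+LH+TRL+R5020 against Antide+LH and from 1 to 2 in Antide+LH+TRL against Antide, and the cholesterol list in Antide+LH against Antide did not pass; the number best matched its own in 6 of 8 arrays of Antide+LH against Antide and in 3 of 8 or fewer of other comparisons, with correlations of -0.09 to 0.03. Of values of named genes past the threshold, 718 held and 175 no longer passed under the alternatives fixed beforehand, 511 held and 396 did not with an array left out, and 33 held and 467 did not under added ones, all with the same direction except 5. These were GAPDH in Antide against Control (0.21) and GAPDH (-0.25) and MCAM (-0.24) in Antide+LH against Antide without the 7 arrays, and -0.05 and -0.08 in the latter with quantile normalization without the 7. Signals near the floor of 16 limit what can be seen of genes such as PGR.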

Other observations

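In the remaining gene lists few members passed. In Antide against Control the apoptosis list had BIRC3 and PMAIP1 rising by 2.32 ± 0.53 and 1.94 ± 0.52 among 17 tested genes (camera adjusted p = 0.719, and 2 rose and 1 fell adjusted over the list alone); BIRC3 inhibits apoptosis and PMAIP1 promotes it. BIRC3 was at the floor on 3 of 4 Control arrays and PMAIP1 on 1, so both changes are lower limits in size, as are those below of BMP2 (1 of 4 Control arrays), GHR (2 of 5 Antide arrays) and ALDOC (1 of 5). Angiogenesis genes had THBS1, an inhibitor of vessel growth, rising by 1.77 ± 0.38 among 20 (camera adjusted p = 0.916, and 1 rose and 2 fell adjusted over the list alone). Among luteal peptide hormones and growth factors, CRHBP and BMP2 rose by 3.51 ± 0.86 and 1.83 ± 0.43, the receptors TGFBR3 (-0.94 ± 0.24) and GHR (-0.92 ± 0.25) fell, and 22 of 26 did not pass (camera adjusted p = 0.393, and 2 rose and 5 fell adjusted over the list alone). In hypoxia and glycolysis, LDHA rose by 1.06 ± 0.28 while ALDOC (-1.69 ± 0.40) and GAPDH (-1.27 ± 0.34) fell, of 14 (camera adjusted p = 0.916, and 1 rose and 2 fell adjusted over the list alone); GAPDH stood at 0.21 without the 7 arrays of high 3'/5' ratio. CCND1, a cyclin, fell by 1.15 ± 0.32 among 19 cell cycle genes (camera adjusted p = 0.877, and 1 fell adjusted over the list alone), and the endothelial marker EMCN (-1.26 ± 0.29) fell among 11 (0.891, and 2 rose and 1 fell adjusted over the list alone). Of 17 progestin and glucocorticoid responsive genes 2 rose, MAOA by 0.96 ± 0.25 and CEBPD, given above, and 0 fell (0.907, and 3 rose and 1 fell adjusted over the list alone). The cholesterol uptake list stood at 0.84 (of 8, LIPA rose and STARD4 fell, and 3 rose and 2 fell adjusted over the list alone), the efflux list at 0.325 (of 10, LPL rose, and 2 rose adjusted over the list alone), collagens at 0.092 (2 of 23 rose, the same adjusted over the list alone) and follicular granulosa cell markers, of which 1 of 7 fell (CYP19A1, and 2 adjusted over the list alone), at 0.226; the mean log2 signal of the granulosa markers differed by -1.08 (exact permutation p = 0.0159, adjusted p = 0.48 over 84 tests).

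In the same comparison no member passed over all genes in the lists of steroid hormone receptors (16 tested, camera adjusted p = 0.548, and 2 rose and 1 fell adjusted over the list alone), prostaglandin synthesis and signalling (7, 0.827), endoplasmic reticulum stress (13, 0.28, and 1 rose adjusted over the list alone), T and NK cells (6, 0.325), neutrophils (3, all higher at a median of 1.56, 0.168), smooth muscle and pericytes (7, 0.871, and 1 fell adjusted over the list alone), fibroblasts and stroma (9, 0.891), red blood cells (3, all lower at a median of -0.96, 0.168), oocytes (3, 0.89) and surface epithelium (4, 0.892). In Antide+LH against Antide, the endoplasmic reticulum stress gene SDF2L1 fell by 1.45 ± 0.41 and the pericyte marker MCAM rose by 1.35 ± 0.38, which turned to -0.24 without the 7 arrays. Also with LH, MMP19 (-1.76 ± 0.47), BIRC3 (-2.24 ± 0.53), BMP2 (-1.84 ± 0.43) and COL6A3 (-1.26 ± 0.31) fell, and GHR (1.07 ± 0.25), TGFBR3 (0.90 ± 0.24) and GAPDH (1.24 ± 0.34) rose; GAPDH stood at -0.25 without the 7 arrays. With 2 of 4 Antide+LH arrays at the floor for BIRC3, 1 of 4 for BMP2 and 2 of 5 Antide arrays for GHR, these 3 changes are lower limits too.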
